A study of Mus musculus with 6 samples.

How the data were processed

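Somite-level tissue of mouse embryos at 9.5 days post coitum was pooled by genotype, and RNA of 3 wild-type and 3 Dll3 mutant pools was hybridised to 6 Affymetrix MOE430A arrays, per the labels. The authors deposited 1 table of 22690 probe sets by 6 pools, in which each value is a linear ratio to a reference of that probe set. The ratio reading comes from the values: 93.4% of rows have a median of 1 (within 0.0015) over the 6 pools, 1497 rows have a lower median and none a higher one, and the values run from 0.266 to 2.498 with 3 decimals. RMA and MAS5 are named per the submitters' processing notes, without version or role, and how the arrays were scaled is not given in the sources used here. A ratio keeps no signal level, so no intensity could be read for a probe set. Whether the rows with a median below 1 are the dim ones was not tested. Of the control probe sets, 19 had such a median. All of them were dap, lys, phe, thr or trp controls, and none were bioB, bioC, bioD, cre, actin or Gapdh controls. A probe set near background can show noise as a difference, and levels of different genes cannot be compared.

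The planned fit assumed log2 RMA values or linear MAS5 signals, which the ratios are not. The unit required changes to the fit. The test used log2 of the ratio with no pseudocount. The variance was not tied to a trend over intensity, since a ratio holds none, and the planned trend, here over the row mean, was kept as an alternative. Both fits had been run when this one was kept as the main one, and neither gave a probe set past the threshold. The value of a gene in the gene lists was the mean of its probe sets in place of the brightest one. The planned filter on dim probe sets and the planned pseudocounts need signal levels and were not run. Whether the later removal of rows with a median below 1 acts as such a filter was not tested.

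The 64 control probe sets were left out, and 22626 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype only, two-sided, Benjamini-Hochberg adjusted p under 0.05). The platform annotation named 1 gene for 20380 probe sets, several for 691 and none for 1555. No gene was named from the last 2 kinds. Through their gene identifiers 20364 probe sets matched the mouse gene table (assembly GRCm38.p6), which was used for names and the order of genes only. The files name no genome build, so no coordinates are given. Gene lists with at least 5 measured genes were tested over 12393 genes with camera (correlation preset to 0.01), with camera at an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other genes. With 3 pools against 3, an exact permutation test cannot go below p = 0.1, and the number of arrays limits the precision.

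The genes named are Dll3, the 8 genes per direction with the smallest unadjusted p where none pass, members of small p for each list described, and Xist and Y-linked genes as a check of the sex mix of the pools. The sex score is the Xist level minus the mean level of Eif2s3y, Kdm5d and Uty. Groups, lists and most alternatives were fixed before the data were examined. A rule for the genes was fixed too, but the list members named were not always those of smallest p, as it required.

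The script was tested on simulated data with the spread of each probe set as moderated by eBayes and 200 changed probe sets among 22626, in 20 runs of mutant against wild-type. It recovered 78.2% of probe sets changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2. False calls made up 6.8% of calls. A list of the size of the trunk Hox list, shifted in simulated independent genes, was found in 20 of 20 runs. These simulations hold no structure shared between probe sets. Their spread, drawn toward a common value by eBayes, also varies less between probe sets than the real one. With fewer than 200 changed probe sets the Benjamini-Hochberg adjustment is stricter, so the recovery does not carry over to few changes. Uncx, at a log2 difference of -0.998 in the real pools, missed the threshold. Figures were drawn with matplotlib 3.10.9.

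Alternatives were the replicate number as a block, the trend, array weights, quantile normalization, median centring, each pool left out in turn, probe sets ending in _x_at or _s_at left out, a robust fit with the trend and other thresholds. Added after seeing the data were the removal of rows with a median below 1, the most variable probe set per gene, the removal of both pools numbered 3 (which were both lowest in 5 of 6 bioB spiked control probe sets, while of the 12 others they were both lowest in 2 and both highest in 3), and the sex score as a covariate, with the preset or an estimated correlation.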

Results

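Gene expression was measured in mouse embryos at 9.5 days post coitum that carried either 2 wild-type copies of Dll3 or the neo insertion allele of Dll3 on both chromosomes. Dll3 encodes a divergent Notch ligand needed for the regular segmentation of somites, the blocks of paraxial mesoderm that give rise to vertebrae and trunk muscle. The tissue lay between the otic placode and the last formed somite, with heart and endoderm taken away, so it held somites together with neural tube and other tissues of that level. RNA from 3 wild-type pools and 3 Dll3 mutant pools was hybridised to 6 Affymetrix MOE430A arrays, 1 array per pool. The series design describes the pools as biological replicates. Each value was a ratio to the probe set's own reference, so levels were compared between pools and never between genes. The number of arrays limits the precision: the median SE of a log2 difference was 0.099.

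The comparison of mutant with wild-type pools asked which genes of somite-level tissue differ when Dll3 is disrupted. Uncx, a homeobox gene of the caudal part of each somite, had the smallest p-value of all probe sets. Its ratio was 1.31 ± 0.108 (SD, n = 3) in wild-type and 0.663 ± 0.115 (SD, n = 3) in mutant pools. All 3 mutant pools lay below all 3 wild-type pools, and the log2 difference was -0.998 (SE 0.127, 95% interval -1.28 to -0.72). Its limma p of 8.05e-06 became an adjusted p of 0.182 over all 22626 probe sets, so Uncx missed the threshold of 0.05, as it did in the fit with a variance trend that had been planned (adjusted p = 0.0545). Adjusted over the list alone, Uncx passed in the list of caudal somite genes (0.000122) and in the sclerotome list (0.000244). Over all probe sets Uncx passed in 3 of its 16 alternatives: with array weights (adjusted p = 0.0309), with the replicate number as a block (adjusted p = 0.0379) and in a robust fit with a trend (adjusted p = 0.048). Its range over the alternatives was 0.0309 to 0.9998. Within each replicate number the log2 difference was -0.84, -1.42 and -0.73.

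No probe set of the 22626 tested passed an adjusted p of 0.05 in limma, and 595 had an unadjusted p under 0.05, of which 313 were higher and 282 lower in the mutant pools. Chance alone would give 1131. The groups did not overlap in 7.5% of probe sets, against 10% by chance. Without wild-type replicate 3 the count at unadjusted p under 0.05 was 1229, without mutant replicate 1 it was 1013, and without wild-type replicate 2 it was 319. With the replicate number as a block it was 1072, and 1 probe set passed the adjusted threshold. Over 18 probe sets for spiked hybridization controls, the residuals of same-numbered pools correlated at 0.84, 0.83 and 0.95, and those of differently numbered pools at 0.68 (wild-type 2 with mutant 1), 0.61 (wild-type 1 with mutant 2) and -0.83 or lower where one was numbered 3, a correlation across probe sets, which are not independent replicates.

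Dll3 itself did not separate the genotypes. Its single probe set had a ratio of 0.997 ± 0.034 (SD, n = 3) in wild-type and 0.983 ± 0.038 (SD, n = 3) in mutant pools. The log2 difference was -0.02 (SE 0.084, 95% interval -0.20 to 0.16). The position of this probe set relative to the insertion is not given in the sources used here, so its level does not check the labels.

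**Figure D1:**
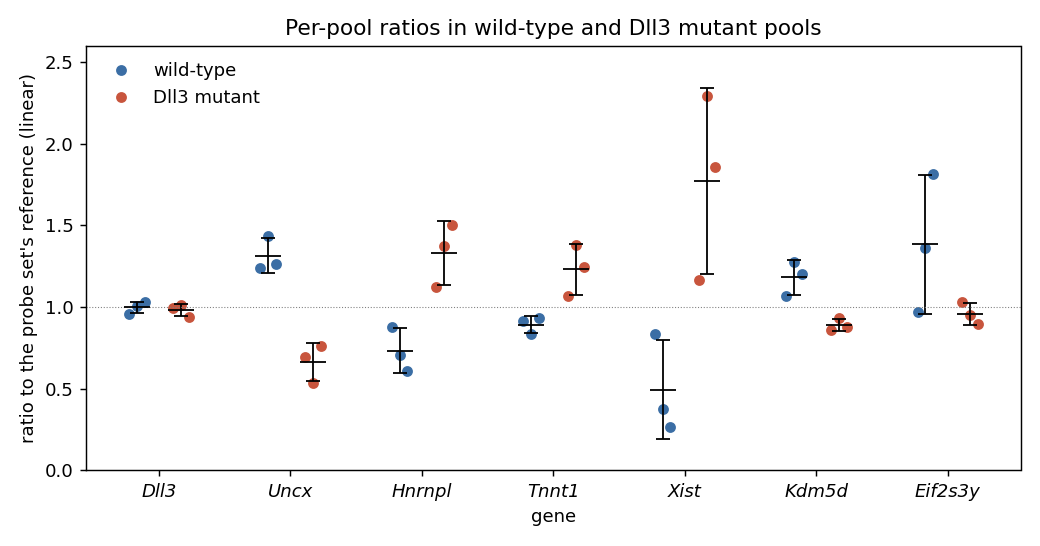
Ratio of each pool to the probe set's reference (linear axis) for 7 genes in 3 wild-type and 3 Dll3 mutant pools, with points for pools and bars for the mean ± SD. The mutant pools lie at 0.536 to 0.76 for Uncx against 1.24 to 1.437 in wild-type, and the groups overlap for Dll3 and Eif2s3y.

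The other genes with the smallest p-values all missed the adjusted threshold, and each had all 3 mutant pools on one side of all 3 wild-type pools. Among those higher in the mutant pools, Hnrnpl, which encodes an RNA-binding regulator of splicing, had a ratio of 0.731 ± 0.137 (SD, n = 3) in wild-type and 1.33 ± 0.195 (SD, n = 3) in mutant pools. Its log2 difference was 0.87 (SE 0.144, adjusted p = 0.94). With the sex score of the pools as a covariate, this difference was 0.34. Kifc1, a mitotic kinesin, was 0.45 higher on the log2 scale, Tnnt1, the slow skeletal troponin T, 0.46, and Sfrp1, a secreted Wnt inhibitor, 0.35. Gprc5b (0.36), Ap5m1 (0.35) and Sh3bgrl3 (0.33) were higher by similar amounts. Lower in the mutant pools were Mapt, the microtubule-associated protein tau (-0.45), the ubiquitin ligase gene Rnf6 (-0.42), the urate transporter gene Slc2a9 (-0.40), Clstn3 (-0.36), the imprinted noncoding RNA Meg3 (-0.36) and the X-linked ubiquitin ligase gene Rlim (-0.33). Other probe sets differed in sign for Rlim, where 3 gave values of 0.02 to 0.14, for Gprc5b (-0.02) and for Mapt (0.05, beside another at -0.15). Those of Ap5m1 (0.045 and 0.025) and Rnf6 (-0.086) kept the sign but lay near 0, with groups that overlapped. Those of Sfrp1 gave 0.06 to 0.22 and those of Meg3 -0.35 to -0.15.

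Genes of somite patterning and Notch signalling were described through lists fixed before the data were examined. In the caudal somite list 7 of 13 genes were higher and 6 lower, with Uncx far from the rest: Efnb2 was at 0.14 and Lfng, a modifier of Notch, at 0.11. In the rostral list 5 of 9 genes were higher, and Mesp2, which sets the rostral identity, was at -0.11 (SE 0.081). In the list of general somite genes 9 of 19 were higher and 10 lower, with a median of -0.001. Among 31 Notch pathway components, 19 were lower and 12 higher: Dlk1 was at 0.35 (SE 0.148) and Pofut1, which fucosylates Notch, at -0.20 (SE 0.086). Notch targets were higher for 11 of 18 genes and lower for 7, with Id1 and Lfng, both among the higher ones, at 0.10 and 0.11. The oscillating genes of the segmentation clock were higher for 15 of 24, led by the Wnt antagonist Dkk1 at 0.20 (SE 0.072). The presomitic list, with Tbx6 at -0.14 (SE 0.099), was lower for 10 of 17. The caudal list had a positive median (0.03) and a negative mean (-0.06), which Uncx sets. No one of these 7 lists passed in camera, with adjusted p-values from 0.487 to 0.875. With the sex score as a covariate the Notch pathway components passed at the preset correlation (median -0.105, adjusted p = 0.0136) and not at an estimated one (adjusted p = 0.843).

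All 13 measured trunk Hox genes (groups 5 to 9), which pattern the body axis, had a negative log2 difference, with a median of -0.18, and the list passed in camera with a preset correlation (adjusted p = 4.58e-07). With an estimated correlation of 0.238 between its genes the list was not past the threshold (adjusted p = 0.775). No single member passed: Hoxd8 was at -0.30 (SE 0.113), Hoxc9 at -0.28 (SE 0.11) and Hoxc8 at -0.26 (SE 0.095). The mean level of the list was 0.15, 0.12 and 0.02 in the wild-type pools and -0.17, -0.02 and -0.02 in the mutant pools on the log2 scale, so mutant replicate 1 was lowest. All 9 anterior Hox genes (groups 1 to 4) were also lower, with a median of -0.08 (adjusted p = 0.044 preset, adjusted p = 0.964 with an estimated correlation). Hoxb1 was at -0.25 (SE 0.118) and Hoxa3 at -0.18 (SE 0.091). Without mutant replicate 1 the median of groups 1 to 4 was 0.018 (adjusted p = 0.915), so its direction rests on that pool. The call also ended without wild-type replicate 1 (adjusted p = 0.0744) or 3 (adjusted p = 0.31), with array weights (median -0.014, adjusted p = 0.433) and with quantile normalization (adjusted p = 0.0848). The posterior groups 10 to 13 had 5 higher and 4 lower genes.

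**Figure D2:**
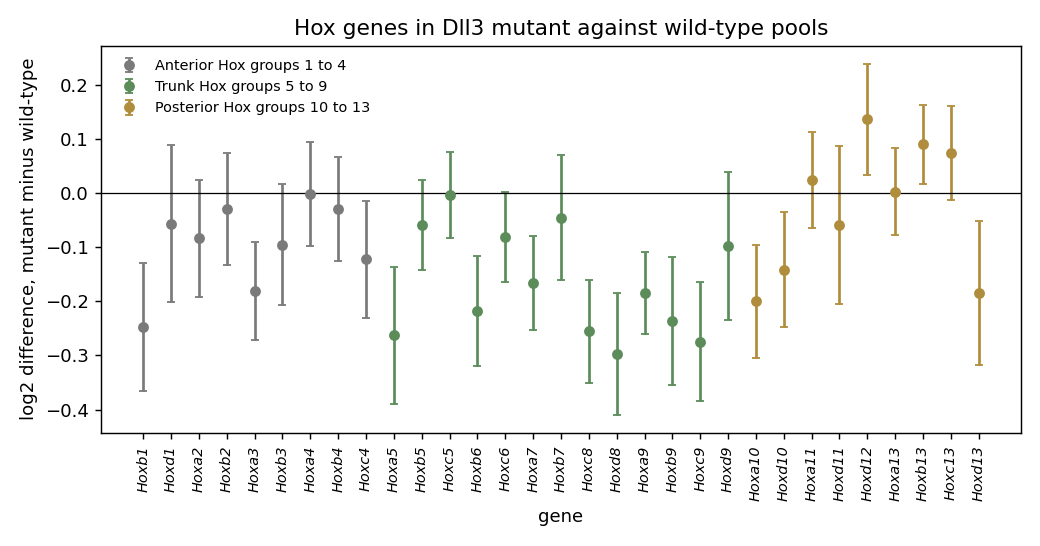
Log2 difference between Dll3 mutant and wild-type pools (mutant minus wild-type, 3 pools each) for the measured Hox genes, ordered by paralogue group, with bars for the SE. All 13 trunk genes and all 9 anterior genes lie below 0, and the posterior genes lie on both sides.

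Of the 42 lists tested, 6 passed in camera with the preset correlation, and none passed with an estimated correlation or with fry. Beside the Hox lists, 14 of 17 primitive erythroid genes were higher (median 0.04, adjusted p = 0.00163, adjusted p = 0.964 with an estimated correlation). They included the embryonic globin gene Hba-x at 0.24 (SE 0.086), the erythroid anion exchanger gene Slc4a1 at 0.28 (SE 0.095) and Hemgn at 0.34 (SE 0.113). This list was not past the threshold without wild-type replicate 3 (adjusted p = 0.175), without mutant replicate 2 (adjusted p = 0.0582) or with the sex score as a covariate (adjusted p = 0.928), and its median was 0.112 without mutant replicate 3, 0.105 without mutant replicate 1, 0.079 without wild-type replicate 1 and 0.068 without wild-type replicate 2. Glycolysis and hypoxia genes were higher for 22 of 26 (median 0.03, adjusted p = 0.0203, adjusted p = 0.964 with an estimated correlation), with Bnip3 at 0.28 (SE 0.118), Slc16a3 at 0.21 (SE 0.095) and Hk1 at 0.19 (SE 0.088). The call of this list ended without wild-type replicate 2 (adjusted p = 0.156) or mutant replicate 3 (adjusted p = 0.108) and with the sex score (adjusted p = 0.369), and its median was 0.017 without wild-type replicate 2, 0.079 without wild-type replicate 3 and 0.061 without mutant replicate 1. Genes of cell adhesion and extracellular matrix were higher for 26 of 35 (median 0.05, adjusted p = 0.0251, adjusted p = 0.964 with an estimated correlation), with the proteoglycan gene Vcan at 0.31 (SE 0.128), Tnc at 0.18 (SE 0.083) and Col5a2 at 0.16 (SE 0.082). That call ended without wild-type replicate 3 (adjusted p = 0.255) or mutant replicate 2 (adjusted p = 0.778) and with the sex score (adjusted p = 0.753), and the median was 0.013 without mutant replicate 2 and 0.086 without mutant replicate 1. BMP and TGF-beta genes were lower for 21 of 29 (median -0.06, adjusted p = 0.0266, adjusted p = 0.775 with an estimated correlation), with Smad9 at -0.27 (SE 0.09), Tgfb3 at -0.23 (SE 0.1) and Bambi at -0.18 (SE 0.088). Of the 8 higher genes, Id4 was at 0.14 (SE 0.09) and Id1 at 0.10 (SE 0.073). Id2 was at 0.08 and Id3 at 0.06. The call of the BMP and TGF-beta list ended without wild-type replicate 1 (0.105) or 3 (0.159), and without mutant replicate 1 (0.0744) or 2 (0.156), and with the sex score (0.221), all adjusted p-values, and the median was -0.037 without mutant replicate 3. Over the 18 alternatives the call ended in 3 for trunk Hox, 10 for anterior Hox, 6 for erythroid, 8 for glycolysis, 7 for adhesion and 11 for BMP genes. The 3 alternatives without the preset correlation ended the call for each of these 6 lists. The other 36 lists had adjusted p-values from 0.101 to 0.97, and 8 of them passed in at least 1 alternative, none of these with an estimated correlation or fry.

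Muscle genes in the dermomyotome and myotome list were at 14 higher and 13 lower (adjusted p = 0.487). The list passed without wild-type replicate 2 (median 0.015, adjusted p = 0.0316) or mutant replicate 3 (median 0.02, adjusted p = 0.0454), with medians of -0.04 to 0.02 over its alternatives, and missed the threshold with all pools at an estimated correlation (adjusted p = 0.964). Adjusted over the list alone, Tnnt1 (0.46, SE 0.1, adjusted p = 0.0251) and Myog, a myogenic regulator (0.30, SE 0.08, adjusted p = 0.0483), passed, and neither passed over all genes. Acta1 was at 0.50 (SE 0.148) and Actc1 at 0.38 (SE 0.152), both actins of striated muscle. Both ratios were highest in mutant replicate 2 (1.72 and 1.571). In mutant replicate 3 Actc1 was at 0.994, inside the wild-type range of 0.832 to 1.006. Among the 13 lower genes were Dmrt2 at -0.23 (SE 0.109) and Myf5 at -0.18 (SE 0.114). Myod1 was at 0.01 (SE 0.09). In the sclerotome list 13 of 26 genes were higher. Cells other than somite were followed through their markers. Neural progenitor genes were higher for 17 of 24 (Fabp7 at 0.27, SE 0.158, with Msx1 lower at -0.15, SE 0.08). Neuronal genes were higher for 16 of 31 (Mnx1, a motor neuron gene, at -0.33, SE 0.122). Surface ectoderm genes were higher for 14 of 18 (Cdh1 at 0.41, SE 0.234), and endothelial genes for 17 of 26 (Gja5 at 0.18, SE 0.078). None of these 4 lists passed in the test used above. At the preset correlation the neuronal list passed in 2 of 18 alternatives, without mutant replicate 2 (median -0.084, adjusted p = 0.000686) and with the sex score (median -0.154, adjusted p = 1.04e-05). The surface ectoderm list passed in 5, at medians of 0.064 to 0.119, among them the replicate block (adjusted p = 0.019) and both pools numbered 3 left out (adjusted p = 0.00303). With an estimated correlation both missed the threshold, without the sex score (adjusted p = 0.964) and with it (adjusted p = 0.843).

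Genes next to Dll3 on chromosome 7 were compared because a targeted allele can carry flanking sequence of another strain. Among 121 measured genes within 100 protein-coding genes on either side, 65 were higher and 56 lower, with a median of 0.016 and a camera p of 0.724. Hnrnpl, 25 genes from Dll3, passed adjusted over the list alone (adjusted p = 0.0119), and the smooth muscle phosphatase inhibitor gene Ppp1r14a, 44 genes away, was at -0.48 (SE 0.144) and did not pass (adjusted p = 0.418). Camera asks for a shift in 1 direction, so it does not cover changes that go both ways. Without regard to direction, the 40 nearest genes, Hnrnpl and Dll3 left out, had a median absolute t at percentile 97 of 10000 random gene sets. The smallest limma p among them was 0.0222.

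The pools also differed in their sex-linked transcripts. Xist, which is transcribed from the inactive X chromosome of females, was at 1.77 ± 0.569 (SD, n = 3) in mutant and 0.493 ± 0.302 (SD, n = 3) in wild-type pools by the probe set of smallest p, a log2 difference of 1.96 (SE 0.352). Its other 2 probe sets differed by 0.80 (SE 0.207) and 1.15 (SE 0.337), with groups that overlapped. The mean Y-linked level was 0.05, 0.25 and 0.47 in the wild-type pools and 0.08, -0.04 and -0.23 in the mutant pools on the log2 scale. Kdm5d, on the Y chromosome, was lower in the mutant pools by one probe set (-0.40, SE 0.095) and near 0 by the other 2 (-0.08 and -0.08). All of these probe sets missed the adjusted threshold. The 401 other X-linked genes had a median of 0.009 (bootstrap 95% interval over genes 0.001 to 0.019). That interval leaves out the spread between pools, and it holds the median over all tested probe sets, 0.0034.

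The first principal component, with 42% of the variance, did not follow genotype. Wild-type replicates 1 and 2 and mutant replicate 1 had scores of -11.5, -8.3 and -15.2, and the other 3 pools had 18.2, 5.39 and 11.4. Component 2, with 17.7%, had higher scores in every wild-type pool than in any mutant pool. The sex scores part the genotypes as well, and 3 against 3 pools part in 10% of cases by chance, so component 2 cannot be tied to genotype.

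**Figure D3:**
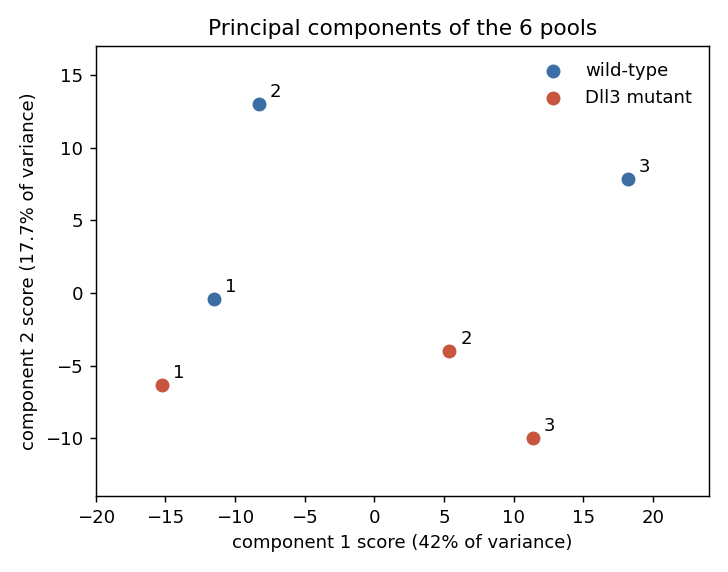
Scores of the 6 pools on principal components 1 and 2 of the log2 ratios, with the percent of variance on each axis, colour for genotype and the replicate number beside each point. Component 1 runs from -15.2 to 18.2 and mixes the genotypes, and component 2 parts the wild-type pools (-0.45 and above) from the mutant pools (-4.03 and below).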

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

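The removal of rows with a median below 1, of both pools numbered 3, the most variable probe set per gene and the sex score (with a preset or an estimated correlation) were chosen after seeing the data. The planned dim filter and pseudocounts were not run, since ratios keep no signal over background. The cause of the differences below was not tested, except that fewer pools enter where a pool is left out. In limma the count of probe sets past the adjusted threshold was 0, with 595 at an unadjusted p under 0.05. It was 1 (Uncx) with array weights, 2 (Uncx and Hnrnpl) with the robust fit with a trend, and 0 with the trend alone, the fit nearest to the planned one (Uncx adjusted p = 0.0545). Leaving out each pool gave 0 to 1 (Xist, without wild-type replicate 1). The count at unadjusted p under 0.05 was 1770 with array weights, 267 with the sex score, and 319 to 1229 with pools left out. Whether the replicate numbers pair the pools stayed open. Over all probe sets residuals of same-numbered pools correlated at 0.37, -0.02 and 0.37, not each above 0.1, and wild-type replicate 2 correlated best with mutant replicate 1 (0.2). Over 18 spiked control probe sets they correlated at 0.84, 0.83 and 0.95, and each pool correlated best with its own number, though pools numbered 1 and 2 also correlated across numbers (0.68 and 0.61), a hint from the data, seen after the fits had been compared, that same-numbered arrays shared a processing step. The fit without the block was therefore kept as planned. With the replicate number as a block the count was 1 (Uncx, adjusted p = 0.0379) and 1072 at unadjusted p under 0.05, and 7 lists passed. The share of probe sets at unadjusted p under 0.05 that were higher was 52.6% in the fit without a block, 48.3% with the block and 38.2% with the sex score. Dll3 was at -0.048 to 0.011 with pools left out, 0.033 without both pools numbered 3 and 0.061 with the sex score. The genes next to Dll3 had medians of -0.009 to 0.032 with pools left out, -0.016 without both pools numbered 3 and -0.051 with the sex score. The count of lists was 6, 3 with the most variable probe set, 0 with an estimated correlation, 0 with fry and 4 to 7 with pools left out. With the sex score the adhesion list turned its test direction (median 0.01, adjusted p = 0.753), and the erythroid (median 0.012, adjusted p = 0.928), glycolysis (0.049, 0.369) and BMP lists (-0.03, 0.221) were not past the threshold. Lists that passed with it and not in the main test at the preset correlation were differentiating neurons (-0.154, adjusted p = 1.04e-05), lateral plate (-0.131, 0.00303), surface ectoderm (0.108, 0.00327) and Notch pathway components (-0.105, 0.0136), and with an estimated correlation beside the sex score no list passed (trunk Hox adjusted p = 0.592). Of 36 lists not past the threshold, 8 passed in at least 1 alternative. Trunk Hox was past the threshold in 15 of 18 alternatives, at medians of -0.331 to -0.143. All 15 kept the preset correlation of 0.01, so the tally does not test that setting. The 3 without it missed the threshold: an estimated correlation (adjusted p = 0.775), fry (adjusted p = 0.986) and the sex score with an estimated correlation (adjusted p = 0.592). Uncx ranged from -1.13 to -0.848 and Hnrnpl from 0.342 to 1.01 over their 16 alternatives.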

Other observations

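The tests of dilution and of the level of the dissection for the Hox genes, and the splits of the pools by counts of probe sets, were chosen only after the results were seen, as was the requirement that each list median keep its side of the bound when any single pool is left out.

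Imprinted genes were at 10 higher and 9 lower of 19, with Meg3 at -0.28 (SE 0.085) and its neighbour Dlk1 at 0.35 (SE 0.148), and the list had an adjusted p of 0.778. Heart muscle genes were higher for 13 of 23, with Tnnt2 at 0.30 (SE 0.1). Yolk sac genes were split 8 to 8, with Rbp4, the retinol carrier, at 0.37 (SE 0.122). No gene or list named here passed the adjusted threshold.

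Uncx was lower in all 3 mutant pools. A smaller share of somite tissue would lower the general somite genes too, and their median was -0.001 (bootstrap 95% interval over genes -0.079 to 0.024, and -0.061 to 0.039 with single pools left out), far above the bound of -0.5. Genes of this list that other cells of the tissue also express would fall less, so a smaller share of somite tissue is made less likely and not excluded. A loss of the whole caudal programme would lower the other 12 caudal genes, and their median was 0.033 (interval over genes -0.016 to 0.058). Caudal genes that other cells of the tissue also express would fall less, so this median cannot exclude such a loss. With the sex score as a covariate the difference of Uncx was -0.848 (interval -1.36 to -0.33, limma adjusted p = 0.9998). The sex scores of the genotypes do not overlap, so that fit cannot tell the sex mix from the genotype. These explanations and chance selection among 22626 probe sets stay open beside an effect of the genotype, which was not tested further. The adjusted p of Uncx in limma was 0.182, and 0.0379 with the replicate number as a block, in a range of 0.0309 to 0.9998 over the alternatives.

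Hnrnpl was higher in all 3 mutant pools. With the sex score as a covariate its difference was 0.342 (interval -0.05 to 0.73), against 0.872 without it and under the bound of 0.436, so a different mix of male and female embryos may account for part of it. A change along the chromosome segment round Dll3 is also a candidate explanation: the 40 nearest other genes had a median absolute t at percentile 97 of 10000 random gene sets, although the smallest p among them was 0.0222. A sequence variant under one probe set cannot be told apart from a change in the transcript, because only 1 probe set names Hnrnpl alone. The sex scores of the genotypes do not overlap (highest -0.085 in wild-type, lowest 0.045 in mutant pools), so these explanations stay open beside an effect of the genotype.

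The trunk Hox genes were lower in the mutant pools in camera with a preset correlation, but not with an estimated one (adjusted p = 0.775) or in fry (adjusted p = 0.986), and 1 other split of the pools had a median of 0.164 in size against 0.184, so the shift itself is uncertain. Primitive erythroid genes were higher for 14 of 17 (mean 0.108, adjusted p = 0.00163 preset, adjusted p = 0.964 with an estimated correlation) and surface ectoderm genes for 14 of 18 (adjusted p = 0.101 preset, adjusted p = 0.964 with an estimated correlation), while lateral plate genes were lower for 13 of 21 (median -0.034, adjusted p = 0.532 preset, adjusted p = 0.964 with an estimated correlation). Dilution by blood, ectoderm or other cells as the whole of the shift is argued against by a median of 0.023 over 43 general somite and neural progenitor genes (interval -0.011 to 0.038), above the trunk Hox median of -0.184. With the sex score as a covariate the difference in the mean trunk Hox level was -0.319 (interval -0.59 to -0.048), against -0.167 without it. The score did not account for the shift in that fit. The sex scores of the genotypes do not overlap, however, so the sex mix cannot be told apart from the genotype. A dissection further to the front in the mutant embryos might lower trunk genes and spare groups 1 to 4, whose median was -0.083 (interval -0.181 to -0.029). That interval would have met the bound first set against this explanation, but it covers genes and not pools, and without mutant replicate 1 the median was 0.018, so it cannot be told apart from the genotype.

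With 10 splits of the 6 pools into 3 and 3, no share under 0.05 can be reached. For probe sets at unadjusted p under 0.05, 8 splits, the real one included, gave as many as the real 595, and the highest other count was 4902, for wild-type replicates 1 and 2 with mutant replicate 1 against the rest, a split with both pools numbered 1 on one side and both numbered 3 on the other, which points to a structure of the samples other than genotype. For probe sets past the adjusted threshold the real count was 0, which all 10 splits reach by necessity, with 0 as the highest other, so nothing follows from it. At an adjusted p under 0.10 the split of highest count gave 756 and the real one 0. For gene lists 2 splits gave 6, the real one and the highest of the others.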
